A study of Drosophila melanogaster with 2 samples.

How the data were processed

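Mcm2-7 is the helicase complex that is loaded on DNA before S phase and unwinds it during replication. Its binding was measured by chromatin immunoprecipitation on a tiling array in Kc167 cells, a Drosophila melanogaster cell line. Per the labels' protocols, cells were held at the G1/S boundary with 1 mM hydroxyurea for 24 h and released for 6 h to reach late S phase. They were fixed with 1% formaldehyde for 10 min, the chromatin was sonicated to about 1 kb, and a monoclonal antibody against the complex was used at a dilution of 1 in 25. Per the labels, immunoprecipitated DNA carried Cy5 and input DNA carried Cy3 on both arrays, so there was no dye swap. The 2 arrays are biological replicates of a single group, and each array carries its own input.

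The authors deposited 4 intensity files, 1 for each channel of each array, with a linear spot intensity and the spot's place on the slide. The median intensity was 642 in each of the 4 files, and the 5th to 95th percentiles spanned 248 to 1861 in the file named 532 and 248 to 1860 in the file named 635 of replicate 1, so the channels had been brought to nearly the same distribution before deposit. The submitters' processing notes name limma, with no version, and the background treatment is not given in the sources used here. The authors also deposited a table with a score per probe and array, which the file header calls a normalised log2 ratio of Cy5 over Cy3, that is ChIP over input. A deposited list of 106 peaks gives the position and a score for each peak, and the peak names point to the MA2C caller. The peaks were given as 1 list for both arrays, and the settings of the caller are not given in the sources used here.

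The intensity files name no probe, so spots were linked to probe IDs through the values. The deposited score of a probe is the log2 ratio of its 2 intensities minus the mean of a probe class, divided by the SD of that class, with 17 classes of 1015 to 32361 probes. This rule linked all 179130 spots to 1 probe ID each, and the largest difference between the rebuilt and the deposited score was 5.0e-07. What defines the classes is not given in the sources used here. The link was tested on simulated data of 20000 spots, where 100% were linked to the right ID. As a separate check, the mean log2 intensity of neighbouring probes on the chromosome had r = 0.284, against 0.00029 in random order.

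The direction of the ratio is likely but not settled. The deposited score has the sign of the file named 532 over the file named 635, and 0 spots could be linked with the ratio turned, whereas Cy5 is the dye read at the longer wavelength. The table header calls the score ChIP over input, and on this ground ratios are given here as 532 over 635 and called ChIP over input. The choice was made after the values had been seen and is opposite to the plan, which took 635 over 532. By then it was known that the authors' peaks and most bins that were extreme on both arrays are positive in the score. Neither settles the direction, since the peaks were called for high signal and the positive excess is itself reported as a result. With the sign turned, above and below input trade places in every statement, and so do the channels called ChIP and input.

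Probe positions were recovered from the probe numbers, which count a grid of 10 bp. On 2L, all 99 peak starts then lay 500 bp before a probe start, and the next best of 6000 offsets placed 28. On 3R, all 7 did so, and the next best of 500000 offsets placed 5, so positions on 3R rest on few peaks. The probes covered 2L from 5741 to 22392451 with 171830 probes and 3R from 17000041 to 17936681 with 7300 probes, at a median spacing of 100 bp. The genome build is not given in the sources used here. No position was therefore matched to a gene, and the planned tests of gene lists, genes and annotation classes were not run.

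For each array the log2 ratio of the deposited intensities was centred on its median, with no further background correction, loess or quantile step. Probes were averaged in bins of 10 kb with at least 5 probes. Each bin and each probe was tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit with an intercept and eBayes, two-sided), with Benjamini-Hochberg adjustment at 0.05. Where eBayes finds no difference in spread between bins, it uses a single pooled spread for all of them, and such a count rests on that assumption. In simulated data, real values were shuffled over probes and 200 of 2293 bins were shifted. The test recovered 51% of shifts of 0.1 and 98% of shifts of 0.2 on the log2 scale, and called 4 unchanged bins. The shuffled noise has no trend along the chromosome or the slide, unlike the real noise. These rates do not carry over to the real bins, where a mean of 0.24 had an adjusted p of 0.736 in the same limma test.

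Peaks were compared with the rest of the tiled sequence by 10000 circular shifts of the peak set along the probes (two-sided). On simulated sites shifted by 0.4 this returned 0.416. Correlations between the arrays were set against every circular shift of 1 array, and they run across probes or bins, which are not independent replicates. The number of arrays, 2, limits the precision of every value. Named items follow a rule fixed before the data were examined: the 10 peaks with the highest score, and the 5 highest and 5 lowest bins of 10 kb. The rule's list of named genes could not be applied.

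Log ratios also followed position on the slide: neighbouring spots had r = 0.407 on replicate 1 and 0.689 on replicate 2. Chromosome order and slide row were unrelated (Spearman rho -0.0016). An alternative chosen after the data were seen removed the class median and the local mean of neighbouring spots (a Gaussian of sigma 3 spots, the spot itself left out). The local mean took away 36.0% and 63.2% of the variance left after the class median. The local mean alone and the class median alone were also tried after the data were seen. The other alternatives were normexp background with offset 50, loess, equal spread of the arrays, centring on the mode, leaving out the dimmest 20% of probes, an intensity trend in eBayes, other bin sizes, the deposited score and the turned sign. The planned correction by probe GC content was not run, because probe sequences and GC content are not given in the sources used here. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots used matplotlib 3.10.9.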

Results

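The series asked where the Mcm2-7 helicase lies on the chromosome in late S phase, as ChIP signal relative to input DNA in Kc167 cells. The data were 2 arrays, 1 for each biological replicate, with 179130 probes over 23.3 Mb of the arm 2L and a short part of 3R. Log2 ratios are given as ChIP over input in the direction stated by the deposited table; the wavelengths in the names of the intensity files point the other way, so this direction is likely but not settled. Positions are in the coordinates of the deposited peak list, whose genome build is not given in the sources used here, and no position was assigned to a gene.

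The authors' 106 peaks were short stretches with ChIP signal above input on both arrays. All 106 had a mean log2 ratio above 0 in replicate 1 and in replicate 2. Over the probes inside peaks the mean log2 ratio was 0.37 ± 0.10 (SD, n = 2 arrays), a 1.29-fold level over input, against -0.02 over all other probes. The difference was 0.43 in replicate 1 and 0.34 in replicate 2, so it exceeded the spread between the arrays. The listed widths had a median of 1276.5 bp and a range of 1044 to 3539 bp, and the peaks covered 150 kb, or 0.645% of the tiled sequence. These values include 500 bp before the first and after the last probe of each peak, and 28 peaks had the width of a single probe with both flanks.

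In the circular-shift permutation test the difference between peaks and the other probes, 0.39 ± 0.07 (SD, n = 2), had p = 0.0001 on each array and on their mean, which is the smallest value that 10000 shifts can give. The list was called by the authors for high signal and is taken to come from these arrays. The direction, the size and the p are therefore largely set by how the list was made and are not independent evidence of binding. Peak means over both arrays ran from 0.22 to 0.57 with a median of 0.37. Across the peaks, the mean log2 ratios of the 2 arrays had a Pearson's r of -0.18. Selection of peaks on signal from both arrays can itself lower this value, so it does not show that the arrays disagree. The rank correlation between the authors' score and the mean log2 ratio was 0.364. These are descriptions across peaks of a list selected on its signal.

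The signal fell off within a few kilobases of the peak centre. Within 0.5 kb of the centre the mean log2 ratio was 0.49 ± 0.01 (SE over 106 peaks) in replicate 1 and 0.35 ± 0.01 in replicate 2. Between 0.5 and 1 kb it was 0.18 ± 0.02 and 0.11 ± 0.01. Between 4 and 4.5 kb it was 0.02 ± 0.01 on both arrays. The mean outside peaks was 0.01 in replicate 1 and -0.04 in replicate 2. Replicate 2 was above its mean outside peaks at that distance, but also at 9.5 to 10 kb (9.3e-05) and at 19.5 to 20 kb (-0.02). Its mean outside peaks therefore does not mark where the signal of the peaks ended. The chromatin had been sheared to about 1 kb, and the central value is raised by the choice of the peaks on their signal.

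**Figure D1:**
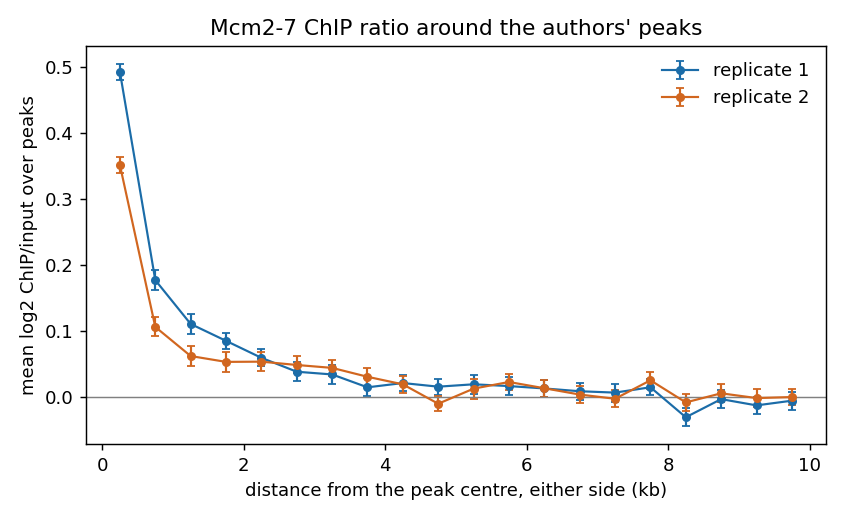
Mean log2 ChIP over input (vertical axis) against the distance from the centre of the authors' 106 peaks in kb (horizontal axis, both sides together) for each replicate; bars are the SE over peaks. Replicate 1 starts at 0.49 and replicate 2 at 0.35 within 0.5 kb of the centre, and both are at 0.02 between 4 and 4.5 kb. Outside peaks the mean was 0.01 in replicate 1 and -0.04 in replicate 2.

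Peaks were spread along 2L, where 37 of 45 bins of 500 kb held at least 1. There were 4.42 peaks per Mb on 2L and 7.47 per Mb on the short 3R segment, which held 7 peaks. Neighbouring peaks were closer than random placement gives. In 10 pairs the gap was 5 kb or less, against a mean of 3.16 pairs in 10000 random placements on the probes (one-sided permutation p = 0.0013). Pairs split by the caller from a single wider site would count here too.

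The peak with the highest score of the authors, 2.68, lay on 2L from 3631521 to 3633570 and had a mean log2 ratio of 0.38 ± 0.12 (SD, n = 2, as in the values that follow). The second by score, on 2L from 5305891 to 5307595, had 0.44 ± 0.07. The third was the widest peak of the list, on 3R from 17475791 to 17479330, with 0.41 ± 0.11. The fourth, on 2L from 16528711 to 16529855, had the highest mean of the 10, 0.51 ± 0.24, but only 5 probes, and 0.34 without replicate 1. The fifth, on 2L from 9568551 to 9571425, had 0.46 ± 0.06. The other 5 began on 2L at 3301481, 14023741, 2751811, 8204361 and 11044661, and their means ranged from 0.36 ± 0.21 at the first of these to 0.46 ± 0.15 at the last. Without replicate 1 the peaks at 3301481 and 14023741 had 0.21 and 0.24, against 0.36 and 0.39 with both arrays.

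**Figure D2:**
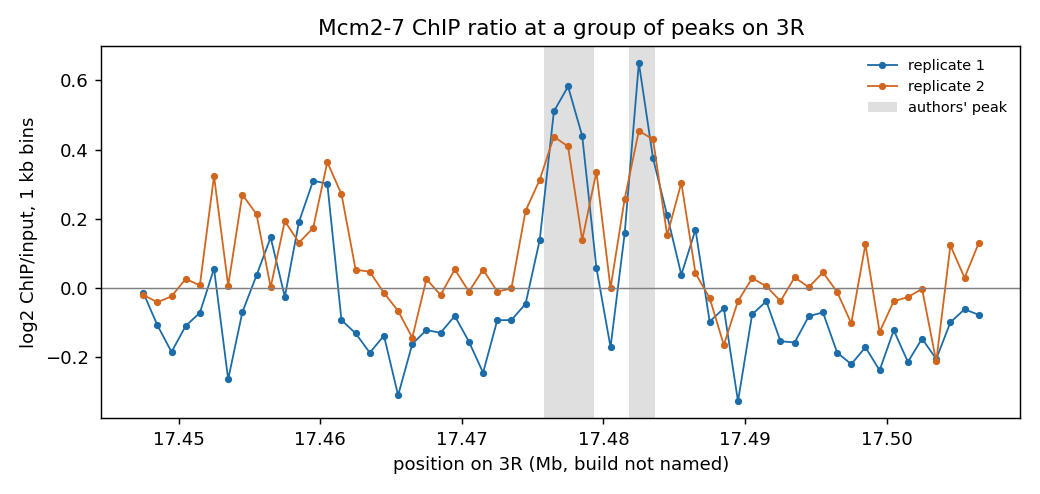
Log2 ChIP over input in bins of 1 kb (vertical axis) against position on 3R in Mb (horizontal axis) for each replicate, with the authors' peaks as grey bands; the region was chosen after the values were seen, because it holds the highest bin of 2 kb. Both replicates rise in the peak from 17475791 to 17479330 and in the peak from 17481781 to 17483665, where replicate 1 reaches 0.65 and replicate 2 reaches 0.45.

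When the tiled sequence was cut into bins of 10 kb, the 5 highest bins all held peaks of the authors and the 5 lowest held none. The peaks were called for high signal, and only 4.75% of all bins of 10 kb were touched by a peak. Neither count is therefore evidence of binding. The highest bin lay on 2L from 19150001 to 19160000, with a mean log2 ratio of 0.24 ± 0.07 (SD, n = 2) and 2 peaks. The next were the bins from 480001 to 490000 with 0.21 ± 0.03 and from 520001 to 530000 with 0.21 ± 0.01, followed by those starting at 2750001 with 0.19 ± 0.14 and at 5290001 with 0.19 ± 0.09. The bin at 2750001 rested on replicate 1, with 0.09 without it. The 5 lowest bins started on 2L at 21340001 with -0.20 ± 0.09, at 19340001 with -0.20 ± 0.12, at 20990001 with -0.18 ± 0.07 and at 16430001 with -0.18 ± 0.03, and on 3R at 17130001 with -0.20 ± 0.22. Without replicate 1 the bin at 17130001, which has 9 probes, had -0.05 and the bin at 19340001, with 8 probes, had -0.11. With the class median and the slide trend removed, a setting described below, the bin at 21340001 went to -0.095 and the bin at 16430001 to -0.113, each a move of more than 1 SD.

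None of these bins passed the test with median centring alone. With limma, 0 of 2293 bins were above input and 0 were below at an adjusted p of 0.05, and the lowest adjusted p was 0.736. Since even the bin with a mean of 0.24 did not pass, the 0 calls do not show that shifts of this size are absent. At an unadjusted p of 0.05, 30 bins lay above and 90 below. Centring on the median left the mean outside peaks at -0.04 in replicate 2 and 0.01 in replicate 1, and the counts below input include that offset. Of the 179130 single probes, 0 passed in either direction, with 8069 above and 10843 below at the unadjusted threshold. After removal of the probe class median and the slide trend, an alternative chosen after the data were seen, 16 bins of 10 kb were above input and 0 below; 13 of the 16 overlapped a peak and 15 were positive on both arrays. The 5 highest bins named above were all among the 16, with adjusted p from 0.00061 to 0.010, and the bin at 19150001 also passed when the arrays were given equal spread (adjusted p = 0.026). At the unadjusted threshold the split turned, to 131 above and 31 below. The removal also moved replicate 2 upward, and these counts may include that move. Over circular shifts of 200 bins of 2 kb, means of replicate 2 ran from -0.076 to 0.024 before the removal and from -0.018 to 0.068 after it. The fit with the slide trend removed pooled the spread over all bins.

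In bins of 2 kb, more bins passed on the positive side of the ratio than on the negative side. Of 11034 bins, 109 were above input and 21 below by limma, and all 109 and all 21 had the same sign on both arrays. That agreement is largely set by the large mean that a call needs, so it is weak evidence of replication. Over all bins of 2 kb the SD was 0.114 in replicate 1 and 0.099 in replicate 2. With the sign turned there would be 21 above and 109 below. The excess on the positive side was seen before the direction was chosen, so it does not support that direction. With the class median and the slide trend removed the counts were 262 and 13, and all 109 but only 5 of the 21 were still called. These counts may include the upward move of replicate 2 given above. The 109 bins had a median log2 ratio of 0.28, and 72 of them overlapped a peak of the authors, while 0 of the 21 did. Of all 11034 bins, 175 overlapped a peak, so 0 of 21 is near the share over all bins. The overlap of the 109 is not independent evidence, since the peaks were called for high signal. The highest bins were those on 3R from 17476001 to 17478000, with 0.49 ± 0.09 (SD, n = 2), and on 2L from 480001 to 482000, with 0.48 ± 0.17. The lowest lay on 2L from 21780001 to 21782000, with -0.35 ± 0.03. For this bin size limma used a single spread for all bins, with an SE of 0.069, so each call rests on the size of the mean and not on the bin's own replicate spread.

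A count that needs no such model also gave more bins on the positive side. Among the bins of 2 kb, 81 were in the upper 2.5% on both arrays, against a mean of 6.90 and a highest value of 29 over all circular shifts of 1 array (one-sided permutation p = 9.1e-05, the smallest these shifts can give). In the lower 2.5% on both arrays there were 13 bins, against a mean of 6.90 and a highest value of 17 (one-sided permutation p = 0.0256). For bins of 1 kb the counts were 141 high and 28 low, each against a mean of 13.3. The highest values over shifts were 70 and 29 (one-sided permutation p = 4.7e-05 and 0.000188). Bins low on both arrays were thus also more frequent than under most shifts, though fewer than those high on both. With the class median and the slide trend removed the counts were 117 and 14 (2 kb) and 205 and 29 (1 kb).

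The replicates were correlated over short distances, and no positive correlation was seen in bins of 50 kb or more. Across probes, Pearson's r was 0.242 and Spearman's rho 0.256. For bins of 1 kb r was 0.267, for 2 kb 0.250 and for 10 kb 0.125. With median centring alone each of these 4 values exceeded every circular shift of 1 array, where the 95th percentile of absolute r was at most 0.067. For bins of 10 kb this did not hold with the class median and the slide trend removed, where r was 0.104 (permutation p = 0.0135, adjusted 0.0203), or with the slide trend alone removed, where r was 0.108 (permutation p = 0.0113, adjusted 0.0170). For bins of 50 kb r was -0.080 (permutation p = 0.177, adjusted over the 6 scales 0.177), and for 500 kb it was -0.35 (permutation p = 0.0426, adjusted 0.0511), so neither passed after adjustment. With the class median and the slide trend removed both passed, at -0.13 (permutation p = 0.0346, adjusted 0.0415) and -0.41 (permutation p = 0.0426, adjusted 0.0426). With the slide trend alone removed neither did, at -0.12 (adjusted permutation p = 0.054) and -0.40 (adjusted permutation p = 0.0511).

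Over broad stretches, the 2 arrays gave different profiles. In replicate 1, bins of 500 kb on 2L ranged from -0.09 to 0.14 with an SD of 0.052, against a median SE of 0.009 over the bins of 10 kb inside them. This SE takes the bins of 10 kb as independent. Their autocorrelation in replicate 1 was 0.638 at 10 kb and 0.393 at 100 kb, so the SE is too small. The highest bins of replicate 1 were 15 to 15.5 Mb with 0.14 ± 0.01 (SE), 4.5 to 5 Mb with 0.12 ± 0.01 and 11.5 to 12 Mb with 0.09 ± 0.01. In replicate 2 the same 3 bins had -0.06, -0.04 and -0.06, and the SD over bins was 0.016. Over the 45 bins on 2L the arrays had r = -0.32 (permutation p = 0.0222, the smallest these shifts can give, not adjusted).

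**Figure D3:**
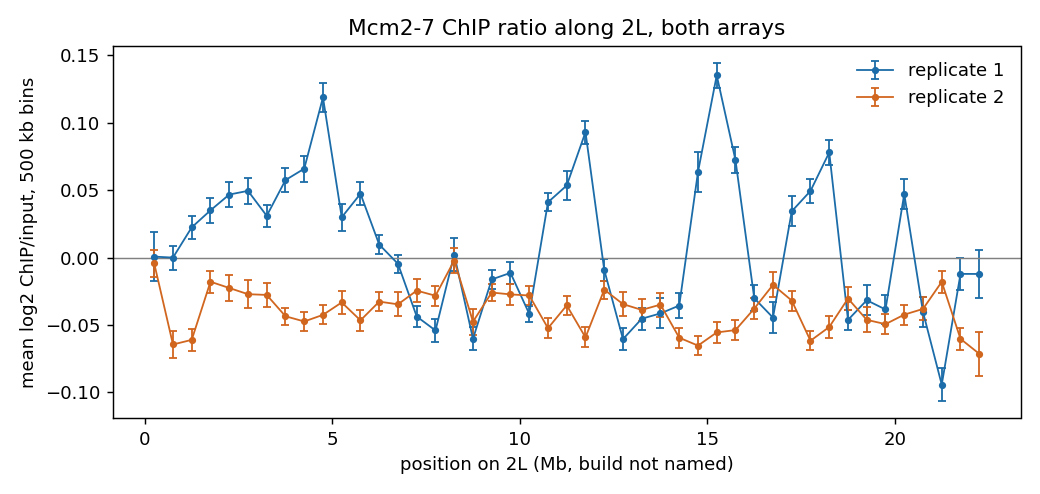
Mean log2 ChIP over input in bins of 500 kb (vertical axis) along 2L in Mb (horizontal axis) for each replicate; bars are the SE over the bins of 10 kb inside. Replicate 1 has broad maxima, the highest of 0.14 at 15 to 15.5 Mb, and replicate 2 stays between -0.07 and 0.00 along the arm.

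No trend along the arm passed the test. The correlation of the bins of 500 kb with position on 2L was -0.37 for the mean of both arrays (permutation p = 0.0667 over all circular shifts), -0.26 in replicate 1 (permutation p = 0.178) and -0.30 in replicate 2 (permutation p = 0.0889). The difference in breadth also showed in the autocorrelation of bins of 10 kb. At a distance of 10 kb it was 0.638 in replicate 1 and 0.372 in replicate 2. At 100 kb it was 0.393 and 0.055, and at 1000 kb it was 0.030 and -0.009.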

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

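The slide-trend, class-median, deposited-score, turned-sign and 1 kb settings were chosen after the data were seen. The rest were planned. The excess in peaks stayed positive and past the threshold in each setting that kept the sign, from 0.34 without replicate 1 and 0.43 without replicate 2 to 0.51 with normexp (1.42 in the SD units of the deposited score); with the sign turned it was -0.39. The 0 bins of 10 kb above input became 1 with equal array spread (2L 19150001), 1 without dim probes (2L 30001), 14 with the slide trend alone removed and 16 with class median and slide trend removed. The 0 below became 1 with the slide trend alone removed (3R 17130001, -0.36 and 0.02 on the 2 arrays). With other bin sizes the counts above and below were 109 and 21 (2 kb) and 178 and 72 (1 kb). They were 124 and 22 (2 kb) and 203 and 89 (1 kb) with the class median alone removed, 245 and 12 (2 kb) and 495 and 34 (1 kb) with the slide trend alone removed, and 262 and 13 (2 kb) and 541 and 38 (1 kb) with both removed. At 50 kb each of these gave 0 and 0. Of the 109 bins, all 109 were among the 262, and 5 of the 21 were among the 13. In the slide-trend fits of bins, the 2 kb fits and the mode-centred 10 kb fit the spread was pooled over all bins, unlike in the main 10 kb fit. At unadjusted p, the split of 30 above and 90 below became 131 and 31 with class median and slide trend removed and 3 and 24 with mode centring. Single probes gave 0 calls in each setting run. Agreement over 500 kb bins moved to -0.24 without dim probes (permutation p = 0.128) and to -0.41 with class median and slide trend removed (permutation p = 0.0426). The correlation with position on 2L, -0.37, ran from -0.41 without dim probes to -0.29 with loess, and was -0.30 without replicate 1 and -0.26 without replicate 2; none passed (permutation p from 0.0667 to 0.178). Causes of these shifts were not tested. Of the values for the 20 named peaks and bins under other processing, 140 moved by less than 1 SD, 20 by more and none changed sign. That SD is the item's own over the 2 arrays and ran from 0.007 to 0.24, so the count does not measure the size of a move. The peak at 3301481 went from 0.36 to 0.52 with normexp, under 1 SD. The bin at 520001 went from 0.21 to 0.22 with loess, over 1 SD. Leaving out 1 array moved 6 of the 20 by over 1.5 times. With 1 array left out, bin counts have no test. Tests of gene lists, genes and annotation classes were not run because the build is unknown, nor was the GC correction, as probe GC is not given. ChIP and input were paired within each array through the ratio, and with 1 group there was no other pairing to use. Signal over background is unknown here, so its limit was not assessed.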

Other observations

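The tests named here were chosen after the results were seen, except the comparison of odd and even probes for the highest bins and that of replicate 2 sites with the replicate 1 profile. Not all bins called above input overlapped the authors' peaks. A bin beside a peak counts as not overlapping. At 1 to 1.5 kb from the peak centres the mean log2 ratio was still 0.11 in replicate 1 and 0.06 in replicate 2. The counts that follow are therefore not counts of separate sites. Of the 109 bins of 2 kb above input, 37 overlapped no peak, and all 109 were positive on both arrays. With the class median and the slide trend removed, 154 of 262 overlapped no peak, and 260 of the 262 were positive on both arrays. In both settings that agreement in sign is largely set by the large mean that a call needs. The highest of the 154, picked after their values were seen, lay on 2L from 15908001 to 15910000, with a log2 ratio of 0.42 ± 0.11 (SD, n = 2). It was followed by 7424001 to 7426000 with 0.36 ± 0.10, 12010001 to 12012000 with 0.36 ± 0.22 and 2196001 to 2198000 with 0.33 ± 0.13. The bin from 16530001, with 0.33 ± 0.08, adjoins a peak. Such bins rest on a spread pooled over all bins, and the 154 may include the upward move of replicate 2 given above.

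Narrow sites shared by both arrays may be real binding or a bias of probes or slide. The 200 bins of 2 kb that were highest on the odd-numbered probes of replicate 1 had a mean of 0.371 there. On the even-numbered probes of replicate 2 they had a mean of 0.0622, above every circular shift (highest 0.024), and 128 of the 200 were above 0. This argues against bias of single probes as the whole source of sites above input, though only a small part of the size carried over. The 200 lowest bins had -0.0537, inside the range of shifts from -0.071 to -0.004, so for sites below input such bias stays open. With the class median and the slide trend removed, the highest bins had 0.130 on replicate 2, with 154 of 200 above 0. The lowest had -0.001, with 103 of 200 above 0, so no carry-over between odd and even probes was seen for them in that setting. With all probes on both arrays, low bins were still shared there. In the lower 2.5% on both arrays there were 29 bins of 1 kb, against a mean of 13.3 over shifts (one-sided permutation p = 0.000235). That count uses the same probes on both arrays, so it cannot separate shared sites from probe bias. Bins of 2 kb above input rose from 109 to 245 when the local slide mean alone was removed. They were 124 with the class median alone removed. The rise does not test slide position, because removing the slide trend also lowers the spread and moves replicate 2 upward. With the class median and the slide trend removed, the SE went from 0.069 to 0.057. With the local slide mean alone removed, the excess in the authors' peaks over the other probes was 0.36, against 0.39. This argues against slide position as the whole source of the signal in peaks, and bins outside peaks were not tested this way. Below input the count of bins fell from 21 to 12, and of the 21 bins only 5 (23.8%) were still called. Their mean went from -0.272 ± 0.004 to -0.147 ± 0.084 (SD, n = 2), while that of the 109 was 0.293 before and 0.299 after. The upward move of replicate 2 may be part of both changes. The count of bins in the lower 2.5% on both arrays uses each array's own percentiles, so that move does not enter it. With the class median and the slide trend removed it was 14 against 13 (2 kb) and 29 against 28 (1 kb). It did not fall, so it gives no sign that slide position made bins low on both arrays. Slide position stays a candidate for part of the 21 called bins, which were not followed in this count. A bias shared by neighbouring probes, such as local base composition, stays open, and no biological explanation was tested because the design has 1 group.

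The broad maxima of replicate 1 were not seen in replicate 2. Over bins of 500 kb the arrays had a negative r, -0.35 (adjusted permutation p = 0.0511). It passed with the class median and the slide trend removed, at -0.41 (adjusted permutation p = 0.0426). With either removed alone, or with the deposited score, it did not pass. No adjusted p was computed for the other settings, such as loess (r = -0.43) and normexp (r = -0.40), each with an unadjusted permutation p of 0.0426. An inverse relation between the arrays thus stays open. Removing the median of each probe class kept 99.6% of the SD of the replicate 1 profile over bins of 500 kb. The r of this profile with the mean intensity of the other 3 channels was -0.393. These values argue against a difference between the authors' probe classes and against intensity as the whole cause. What defines the classes is not given, so base composition itself was not tested. The profile followed the departure from replicate 2 of the numerator channel of replicate 1 (r = 0.906) more than that of its denominator channel (r = -0.173). Part of each value is arithmetic because the ratio contains both. A candidate explanation is a difference in the DNA hybridised in that channel, which is ChIP DNA in the likely direction and input DNA if the sign is turned. Which of these it is, and what made it differ, stays open.

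A hypothesis was that narrow sites of replicate 2 would be more frequent where replicate 1 was broadly high. Over the 45 bins of 500 kb on 2L, Spearman's rho was -0.203 (permutation p = 0.244, adjusted 0.367 over 3 relations), so no positive relation was seen. The number of the authors' peaks per bin had rho 0.019 with replicate 1 (permutation p = 0.867, adjusted 0.867) and 0.405 with replicate 2 (permutation p = 0.0222, the smallest the shifts can give, adjusted 0.0667). The peaks were called for high signal and their probes are part of these bin means. A positive relation is therefore partly built in and is not independent evidence.

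All 4 channels, input included, dropped sharply at 1.35 Mb on 2L. Between the 200 kb before and after, log2 intensity relative to the probe class changed by -0.72 and -0.69 in the numerator and denominator channels of replicate 1 and by -0.66 and -0.68 in those of replicate 2, a 1.61-fold drop. It was the largest step of 880 positions on 2L, the next elsewhere being 0.47. Adjustment for probe class kept 101% of it, which argues against a difference between these classes but leaves base composition untested, and the difference between the adjoining bins of 25 kb was 120% of the step. A sharp change of this kind in both inputs is consistent with a change of copy number in this cell line, a hypothesis that these arrays cannot separate from a boundary in probe behaviour without another cell line; the log2 ratio itself moved by -0.03 in replicate 1 and 0.02 in replicate 2 there.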
